A study of Mus musculus with 4 samples.

How the data were processed

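Histone marks were profiled by chromatin immunoprecipitation on 2-colour promoter microarrays (SurePrint G3 mouse, Agilent) in wild-type C57BL/6J mouse cells. H3K4me3, trimethylation of lysine 4 of histone H3, marks active or poised promoters, and H3K27me3, trimethylation of lysine 27, is laid down by the Polycomb repressive complex. Each mark was measured in cultured astrocytes and in neural stem cells (NSC), with 1 array per mark and cell type and 4 arrays in all. Per the labels' protocols, formaldehyde-fixed chromatin was sonicated and precipitated, the DNA was amplified by whole-genome amplification, ChIP DNA was labelled with Cy5 and the comparison DNA with Cy3. The sample characteristics give the Cy3 channel as input DNA, while the labelling protocol names both input and pan-H3 precipitated DNA for that dye. The values are described here as ChIP over input, and a pan-H3 denominator is not excluded.

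The labels disagree in one respect. Titles, source names and cell-type fields separate astrocytes from NSC, while the growth text gives embryonal brain for the arrays titled astrocyte and glial cells for those titled NSC. Groups were taken from the titles, and every direction below holds for the arrays as titled.

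The authors deposited one value per array feature on a log scale, taken here as log2 of Cy5 over Cy3. The submitters' processing notes name Agilent Feature Extraction. Its version, the normalization, any filter, the genome build and the base of the logarithm are not given in the sources used here. The values reach from -6.98 to 6.80 on the astrocyte H3K4me3 array, a span too wide for log10 ratios of scanner signals; a natural logarithm cannot be excluded, and every size printed would then be on that scale. As deposited, the array medians over genomic probes were 0.02 for astrocyte H3K4me3, -0.10 for NSC H3K4me3, 0.10 for astrocyte H3K27me3 and 0.06 for NSC H3K27me3. The centring and scaling behind these medians remain unknown. The direction rests on the dyes in the labelling protocol. No signal intensities, backgrounds or flags were used here, so the precision of single probes is limited by the number of arrays and the signal behind each ratio is unknown.

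The table held 416348 features with no missing value. The 1377 features without a genomic probe name (0.331%) were left out of all comparisons. Each array was centred on the median of its 414971 genomic probes. The sources used here do not pair probes with genes or genomic positions, so no gene or coordinate is named. The analysis planned per gene, its lists of marker genes and the centring on olfactory and vomeronasal receptor and keratin-associated genes were not run. The same thresholds were applied to single probes. A probe was called marked at a centred log2 ratio of at least 1. It was called different between cell types where NSC and astrocyte levels differed by at least 1 and the higher level was at least 1. The probes named by identifier are the 2 with the largest difference in each direction for each mark. The thresholds and the number of probes to name were set before the data were examined. They were set for means over genes, which also needed at least 75% of probes in the direction. Their use on single probes, without that condition, was adopted because probes were not paired with genes.

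Probe identifiers carry a running number. Probes were joined into stretches where successive numbers differed by at most 4, which held for 95.5% of steps. Of 18633 stretches, the 16531 with at least 3 probes were used; they held a median of 26 probes (interquartile range 18 to 32). Stretch levels are means over probes with the standard error over probes, which is no replicate error. A stretch was called different by the same rule when also at least 75% of its probes differed in that direction. The use of stretches was chosen after the data were seen, on the basis of the correlation between neighbouring numbers. The genomic distance between neighbouring probes is not given, so lengths are in probes.

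With 1 array per group no test across samples can be made and no p-value is given. Comparisons are described by their size, by the noise of single probes and by lists of stretches drawn at random. The noise was estimated from the differences between probes with successive numbers. It was 0.80 (SD of the NSC minus astrocyte difference) for H3K4me3 and 0.28 for H3K27me3. The estimate includes real change between neighbours and leaves out errors that neighbours share. Wilson 95% intervals on shares of probes cover counting error only, and neighbouring probes are not independent. Random lists (10000 per comparison) were drawn from stretches without a difference and matched in 40 bins of mean H3K4me3 level. The calling rule was tested on simulated data for all 414971 probes. The simulated changes were increases in one cell type, placed only at probes with a high mean level over both cell types. Recovery at probes with low levels was not tested. Of 200 simulated H3K4me3 changes, it recovered 75% at a size of 1.5 and 100% at a size of 3, and it called 9.05% of unchanged probes at the estimated noise. For H3K27me3 it recovered 96% at 1.5 and 100% at 3 and called 0.00386% of unchanged probes.

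Alternatives covered the centring and scaling of arrays, the thresholds, smoothing and the use of stretches. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.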

Results

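H3K4me3 and H3K27me3 were mapped on promoter arrays in astrocytes and in neural stem cells (NSC) of wild-type mice, with 1 array for each of the 4 combinations. The series concerns a mouse glioma model, and these arrays describe normal cells of the neural lineage. Each array gave 414971 genomic probes, and levels are centred log2 ratios of ChIP over input DNA. There were no replicates, so no difference below has a replicate error or a p-value.

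Astrocytes and NSC carried H3K4me3 on a similar share of promoter-array probes and shared most of it. The mark was present on 33.8% of probes in astrocytes (140079 probes; Wilson 95% interval 33.6 to 33.9) and on 31.3% in NSC (129820 probes; 31.1 to 31.4). Both cell types had it on 108939 probes, 26.3% of the total. H3K27me3 covered a much narrower range. Its levels reached 1 on 0.636% of probes in astrocytes (0.612 to 0.660) and 0.668% in NSC (0.643 to 0.693), and a level of 0.58 (1.5-fold over the array median) on 8.71% and 8.58%. The standard deviation over probes was 2.09 and 1.57 for H3K4me3 in astrocytes and NSC, against 0.67 and 0.59 for H3K27me3.

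**Figure D1:**
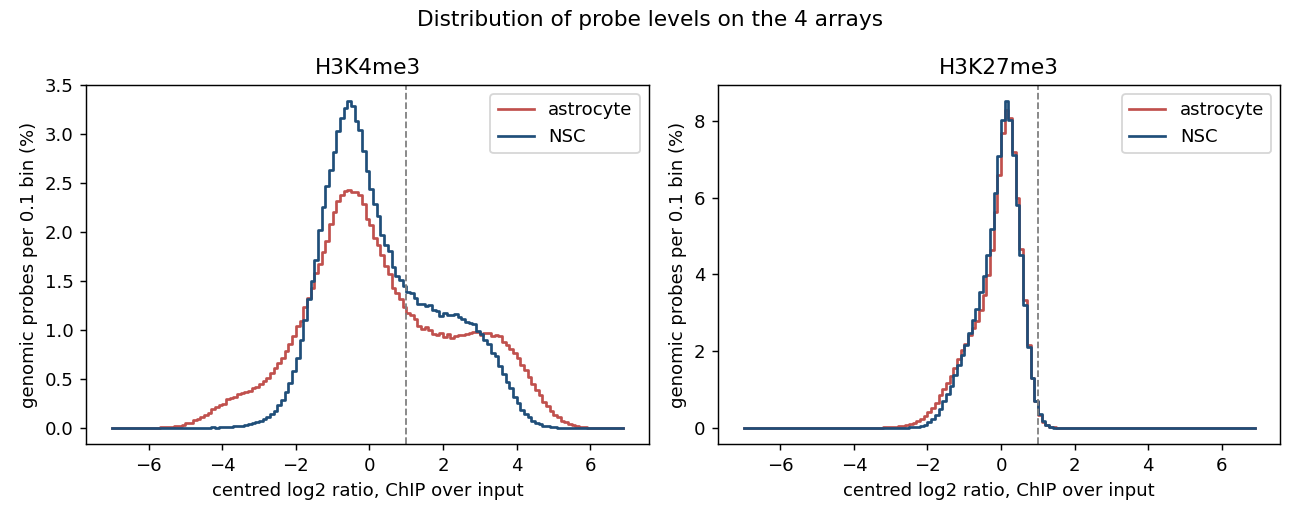
Percent of genomic probes per 0.1-wide bin (vertical axis) by centred log2 ratio of ChIP over input (horizontal axis), for H3K4me3 (left) and H3K27me3 (right) in astrocytes and NSC, 1 array each. The dashed line is the level of 1 used for a marked probe; 33.8% and 31.3% of probes lie above it for H3K4me3 and under 1% for H3K27me3.

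The same mark agreed between cell types and the marks opposed each other. Across probes, Pearson's r between astrocytes and NSC was 0.79 for H3K4me3 and 0.75 for H3K27me3. Between the marks r was -0.49 within astrocytes and -0.49 within NSC, and across cell types it was -0.64 for NSC H3K4me3 with astrocyte H3K27me3 and -0.38 for the reverse pair. Probes are not independent replicates, and these coefficients describe the arrays only. Because the ratios of different marks correlated clearly below 0, their direction rests on the stated dyes, with Cy5 for the ChIP DNA on all 4 arrays.

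Values followed the running number of the probes. Within stretches, neighbouring probes correlated at 0.78 for astrocyte H3K4me3, 0.86 for NSC H3K4me3 and 0.68 for H3K27me3 in each cell type. Across steps of over 100 numbers the correlation was 0.02 and 0.10 for H3K4me3 in astrocytes and NSC, and 0.20 and 0.16 for H3K27me3. In the 13451 stretches with at least 15 probes, H3K4me3 was highest in the middle. Its mean over the middle of each stretch (parts 5 and 6 of 10) was 0.97 in astrocytes and 0.72 in NSC, against -0.43 and -0.12 over the outermost probes (the first and last of 10 equal parts). H3K27me3 was slightly lower in the middle than at the ends, by 0.11 in astrocytes and 0.07 in NSC.

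The comparison of H3K4me3 between NSC and astrocytes asks where the active-promoter mark differs between a stem cell and a differentiated glial cell. At single probes, 48399 were higher in astrocytes and 15811 were higher in NSC, so that 24.6% of the differing probes were higher in NSC (Wilson 95% interval 24.29 to 24.96). Probes higher in astrocytes had a median level of 2.71 in astrocytes and 1.07 in NSC. Those higher in NSC had a median of 1.55 in NSC and -0.08 in astrocytes. Where both cell types were marked, the NSC level was lower by a median of 0.53 (interquartile range of the difference -0.96 to -0.09), and its direction depended on the scaling. The median difference was -0.64 without centring and -0.44 with mode centring, but 0.03 after quantile normalization and 0.24 with equal median absolute deviations.

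This split depended on how the arrays were scaled. Scaled to the same median absolute deviation, 60.2% of differing probes were higher in NSC, and after quantile normalization 49.8% were. The differing probes made up 15.5% of all probes. Simulated noise alone gave 9.05%. This is no bound, because the noise estimate includes real change between neighbours but leaves out errors that neighbours share. The simulation also used the same noise at all levels. Of the called probes whose next number is on the array, 96.5% had a neighbour that differed in the same direction.

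The nearest neighbours of the probes with the largest differences differed in the same direction, to different extents. At each of these probes the lower level lay below the 1st percentile of its H3K4me3 array (as deposited, -4.17 in astrocytes and -2.54 in NSC). The ranking thus picked extreme low readings. A_68_P29322394 had a level of 2.11 in NSC and -5.63 in astrocytes, and its 4 nearest probes were higher in NSC by 2.65 ± 2.26 (SD over 4 probes); its whole stretch of 29 probes was higher by 1.20 ± 0.37 (SE over probes). A_68_P31962512 had 2.00 in NSC and -5.56 in astrocytes, with 1.43 ± 0.93 at its 4 nearest probes, while the mean difference over its stretch of 41 probes was -0.26 ± 0.27, not above 0. In the other direction, A_68_P29517389 had 3.26 in astrocytes and -3.07 in NSC, and the NSC minus astrocyte difference was -3.02 ± 0.77 at its 4 neighbours and -1.38 ± 0.46 over its stretch of 17 probes. A_68_P24467750 had 1.53 in astrocytes and -4.88 in NSC, and its 2 nearest probes gave a difference of -0.46 ± 0.20 and its stretch of 33 probes -0.63 ± 0.31.

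**Figure D2:**
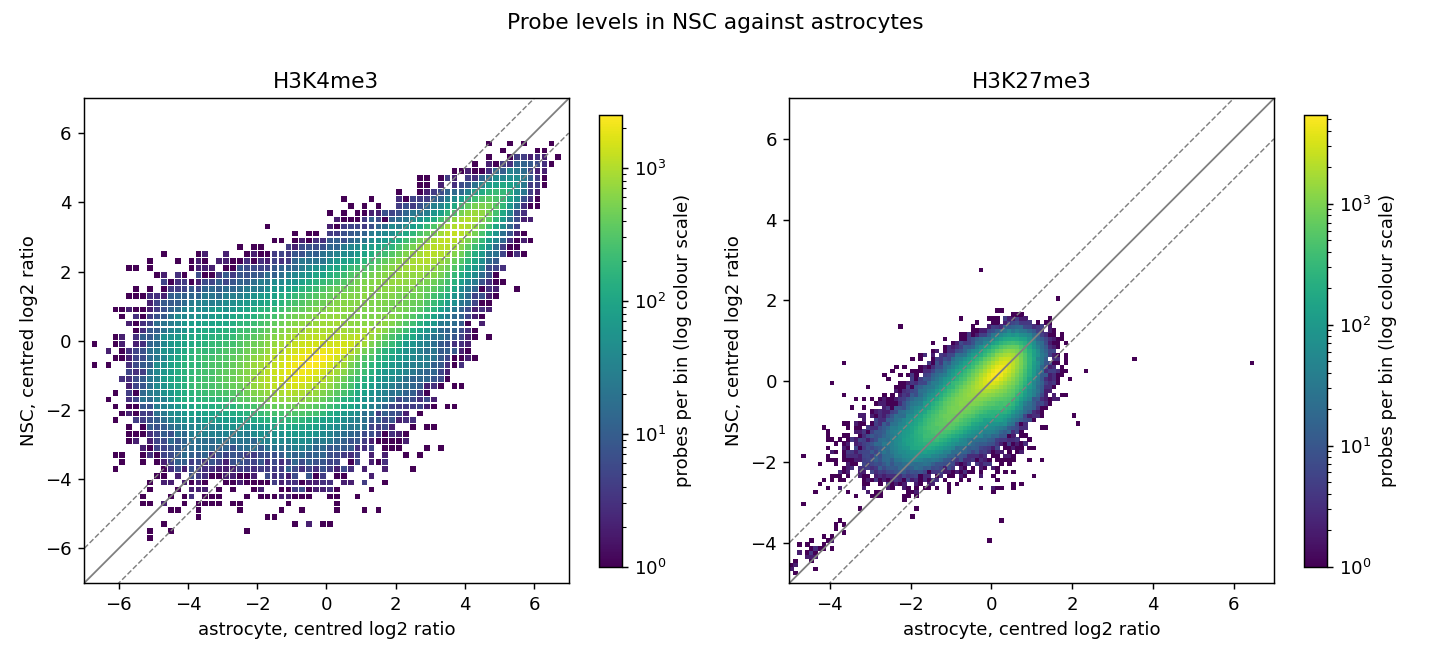
Centred log2 ratio in NSC (vertical axis) against astrocytes (horizontal axis) for H3K4me3 (left) and H3K27me3 (right), with colour giving the number of genomic probes per bin on a log scale. The solid line is equality and the dashed lines a difference of 1; probes marked by H3K4me3 in both cell types lie mostly below equality, by a median of 0.53, which turns to 0.03 above it after quantile normalization.

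By means over whole stretches, few stretches were called different in H3K4me3. Of 16531 stretches, 195 were higher in astrocytes and 70 were higher in NSC. The astrocyte group had median levels of 1.75 in astrocytes and 0.47 in NSC, and the NSC group 0.24 in astrocytes and 1.52 in NSC. The largest difference in the astrocyte direction was a stretch of 19 probes at 2.64 in astrocytes and -0.10 in NSC, a difference of -2.74 ± 0.23 (SE over probes), with 100% of its probes lower in NSC. The largest in the NSC direction spanned 4 probes at 2.93 in NSC and -0.10 in astrocytes, a difference of 3.03 ± 0.58. The median SE over probes of a stretch difference was 0.23. After quantile normalization 217 stretches were higher in NSC and 102 in astrocytes, so the balance between the directions is not settled by these arrays. The rule needs a stretch mean of at least 1, reached by 4889 stretches in astrocytes and 5560 in NSC. A mean over a median of 26 probes can dilute a difference at a peak. By the mean of the 3 highest probes of each stretch, 3758 were higher in astrocytes and 35 in NSC. The few calls therefore do not show that H3K4me3 differed at few places.

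H3K4me3 in NSC reached farther from its peaks than in astrocytes. Probes marked in both cell types had mean levels of 3.02 in astrocytes and 2.49 in NSC, and stretches with no such probe lay at -1.02 and -1.07; after quantile normalization the marked levels were 2.75 in each cell type. At 5 probes from the nearest marked probe, the level was -0.74 ± 1.31 in astrocytes and 0.02 ± 0.64 in NSC (SD over 12611 probes). As a share of the range between unmarked and marked level, 6.77% was left in astrocytes and 30.5% in NSC. After quantile normalization these shares were 6.40% and 33.2%. Runs of marked probes themselves were longer in astrocytes, at a mean of 7.18 probes (18351 runs of 2 or more) against 6.51 in NSC (18875 runs). Runs of 10 or more probes made up 27.8% in astrocytes and 21.1% in NSC, and the mean was higher in astrocytes in each other setting. The farther reach in NSC thus concerned mean levels under the marked level of 1.

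**Figure D3:**
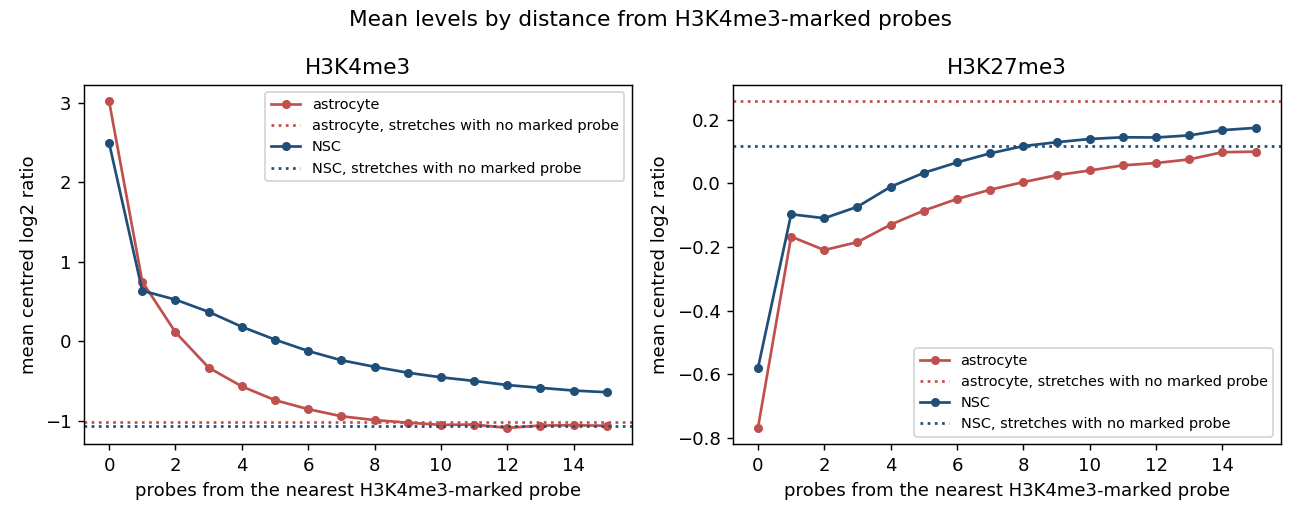
Mean centred log2 ratio (vertical axis) of H3K4me3 (left) and H3K27me3 (right) by the number of probes to the nearest probe marked by H3K4me3 in both cell types (horizontal axis). Dotted lines are the mean in stretches without such a probe; at 5 probes the H3K4me3 mean is -0.74 in astrocytes and 0.02 in NSC.

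For H3K27me3, the number of differing probes was set largely by the narrow range of the mark. At a difference and a level of at least 1, 646 probes were higher in astrocytes and 287 in NSC, 0.225% of all probes, against 0.00386% called from simulated noise. Under 1% of probes reached that level on either array. The simulated share is no bound, for the reasons given for H3K4me3. Its difference had an SD of 0.28, against 0.45 over all probes in the data. The simulated noise was also normally distributed, which rarely gives outlying single probes. The gap between the shares is thus set in part by the simulation. At a difference and a level of at least 0.58, 10822 were higher in astrocytes and 7525 in NSC. Without a requirement on the level, 7734 probes were higher by 1 in astrocytes and 8008 in NSC. Stretch means could not be compared by this rule, since 1 stretch in astrocytes and 0 in NSC reached a level of 1. Of the 461 called probes whose next number is on the array, 93.1% had a neighbour that differed in the same direction. The median difference of these neighbours in the direction of the call was 0.76. The probes with the largest differences, in contrast, often stood alone. A_68_P20405140 read 6.48 in astrocytes and 0.49 in NSC, a difference of -5.99, while its 4 neighbours gave 0.25 ± 0.17. A_68_P26218156 and A_68_P31304300 were higher in NSC by 3.62 and 3.00, and their neighbours differed by 0.05 ± 0.19 and 0.17 ± 0.28. At A_68_P24488818, with 1.06 in astrocytes and -2.35 in NSC, the 4 neighbours were also higher in astrocytes, with an NSC minus astrocyte difference of -0.80 ± 0.20.

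At the lower level of 0.58, astrocytes had more stretches covered by H3K27me3 than NSC. The stretch mean reached it in 593 stretches in astrocytes and 273 in NSC, with 50 in common. The order was kept in each other scaling, but the counts were not: 584 and 274 after quantile normalization (48 in common), 502 and 338 with equal median absolute deviations (43), 1451 and 582 without centring (200), and 87 and 21 with mode centring (0). Over all stretches H3K27me3 was higher in NSC in 62.5%, with a median difference of 0.08 (54.6% and 0.025 after quantile normalization, 56.9% and 0.041 without centring or with mode centring), and single probes at 0.58 were about as many in astrocytes (36139) as in NSC (35614). The levels depended on the distance from H3K4me3. In stretches without a probe marked by H3K4me3 in both cell types, the mean H3K27me3 level was 0.26 ± 0.42 in astrocytes and 0.12 ± 0.46 in NSC (SD over 123559 probes). In the other stretches NSC had the higher mean at each distance from 0 to 15 probes, for example 0.03 against -0.09 at 5 probes.

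The promoter states ask how often both marks lie on one promoter, the bivalent state described in stem cells. Probes with both marks were rare in both cell types. There were 263 in astrocytes and 174 in NSC, where marks placed independently would have given 890 and 867. With an H3K27me3 level of 0.58 the counts were 2592 in astrocytes and 2102 in NSC, against 12199 and 11142 for independent marks. At a level of 1, H3K27me3 alone was found on 2375 probes in astrocytes and 2597 in NSC, and neither mark on 65.7% and 68.1% of probes. Few probes passed this H3K27me3 level on both arrays of that mark. The level lay at the upper edge of H3K27me3, reached by 0.636% of probes in astrocytes and 0.668% in NSC. At this level 135 probes had H3K27me3 alone in both cell types, and 6 had both marks in both. At an H3K27me3 level of 0.58, 10050 probes had H3K27me3 alone in both, 30.0% of those with it alone in NSC. A small shift can move a probe across such a level, so these counts do not show that the other probes changed state. Among whole stretches, 1 in astrocytes and 0 in NSC carried H3K4me3 at 1 and H3K27me3 at 0.58, where a count of 0 allows up to 0.0181% of stretches. The array averages a cell population, so a probe with both marks need not carry them in the same cell.

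H3K27me3 was lowest at the probes with the most H3K4me3. In astrocytes its median was 0.19 at probes with an H3K4me3 level below -1, 0.13 from -1 to 1, -0.28 from 1 to 3 and -0.85 at 3 or more. In NSC the medians were 0.08, 0.17, -0.38 and -0.86.

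Most stretches that differed in H3K4me3 differed the opposite way in H3K27me3, at low levels of H3K27me3. Of the 195 stretches with more H3K4me3 in astrocytes, 180 had less H3K27me3 in astrocytes, with a median NSC minus astrocyte difference of 0.28. The other 15 made up 7.69%, against 14.4% to 25.6% in lists matched on H3K4me3 level, so most matched stretches also had less H3K27me3 in astrocytes. The matched lists had medians between 0.12 and 0.18 (middle 95% of 10000 lists). Of the 70 stretches with more H3K4me3 in NSC, 46 had less H3K27me3 in NSC (65.7%, against 12.9% to 31.4% in matched lists). Their median difference was -0.17, against 0.09 to 0.19 in matched lists. Both medians lay outside all 10000 matched lists. The median H3K27me3 levels were -0.29 in astrocytes and 0.05 in NSC in the 195 stretches. In the 70 stretches they were -0.47 in astrocytes and -0.60 in NSC, and 24 of the 70 did not go the opposite way. These levels lay near or below the array median, so the differences do not show a gain or loss of marked H3K27me3. After quantile normalization the medians were 0.32 for 102 stretches and -0.18 for 217 stretches.

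Across single probes, compared without matching on H3K4me3 level, an opposite relation was seen only at probes with more H3K4me3 in astrocytes. The 48399 probes with more H3K4me3 in astrocytes had a median H3K27me3 difference (NSC minus astrocyte) of 0.11, with 33.8% lower in NSC, against 0.05 and 45.1% at probes without an H3K4me3 difference. The 15811 probes with more H3K4me3 in NSC had a median of 0.14, with 38.0% lower in NSC. The H3K27me3 difference itself depended on the H3K4me3 level. Its means were -0.77 in astrocytes and -0.58 in NSC at probes marked in both, and 0.26 and 0.12 in stretches without one. These unmatched groups therefore do not separate the level from the change. Over all probes the differences of the 2 marks had a Pearson's r of 0.0036 and a Spearman's rho of -0.0012. Over stretches r was -0.09 and rho -0.14. Probes with more H3K4me3 in NSC and more H3K27me3 in astrocytes numbered 9, against 24.6 for independent calls. Those with more H3K4me3 in astrocytes and more H3K27me3 in NSC numbered 42, against 33.5. Probes with more of both marks in NSC numbered 24 against 10.9, and with more of both in astrocytes 48 against 75.3. With an H3K27me3 difference and level of at least 0.58, the 4 counts in the same order were 119 against 412, 680 against 878, 280 against 287 and 397 against 1262. The excess of 2 of the 4 combinations was thus not kept at the lower threshold. The independent counts are no neutral reference, because each call needs a minimum level and the marks seldom reach theirs on the same probe. At an H3K27me3 level of 0.58 both marks lay on 2592 probes in astrocytes, against 12199 for independent marks. The deficits restate this exclusion at least in part, so these counts say little on whether the changes oppose each other.

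**Figure D4:**
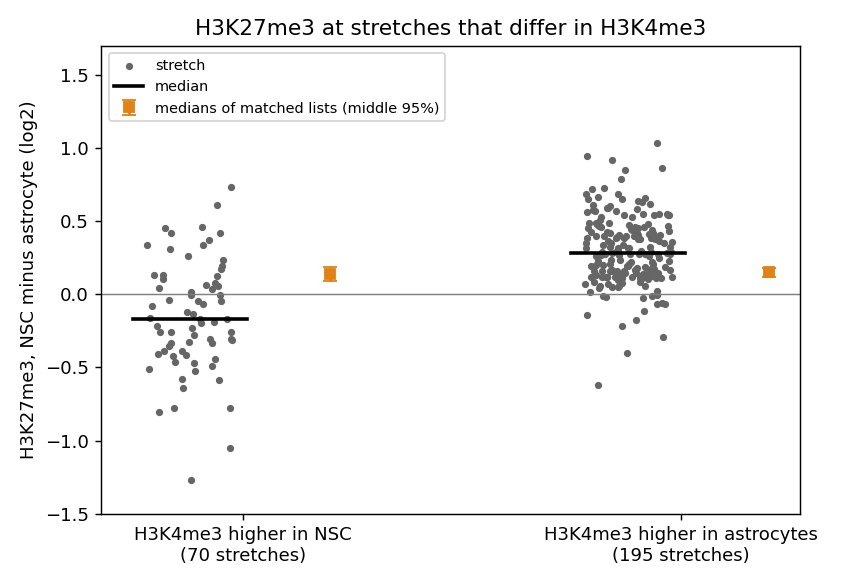
NSC minus astrocyte difference of H3K27me3 (vertical axis, log2) in stretches with H3K4me3 higher in NSC (70) or in astrocytes (195). Grey points are stretches, black bars their medians (-0.17 and 0.28), and orange squares with bars the median and middle 95% of medians of 10000 matched lists.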

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

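Of the features left out as array controls, 16 of the 677 in the series named SRN reached an H3K4me3 level of at least 1 on both arrays (2.36%). This was seen in 0 of 481 features named GD, 0 of 100 named DCP and 0 of 77 negative controls named NC2. The DCP and NC2 features are too few to tell a share of 2.36% from none.

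The scaling and neighbour tests of the first pattern and the shifted-probe test of the third had their expected outcomes written before their values were computed. The equal floor and marked level and the tests of the second pattern were chosen after the data were seen. The first pattern is the excess of H3K4me3 calls higher in astrocytes. Noise of single probes is argued against as the source of the calls as a set. Neighbours that were not themselves called differed by a median of 0.74 in the direction of the call, with 92.3% of them on its side. This held for calls higher in NSC (89.9%) and higher in astrocytes (93.2%). The test therefore cannot tell why 1 direction had more calls, and noise may still account for part of them. A difference in the spread of the arrays stays open. Equal scaling moved the share higher in NSC to 60.2%, past balance and just outside the range of 40% to 60% set for that cause. Setting the floor and marked level equal gave 54.2%. That scaling removes the mean difference at marked probes by construction, so the loss of the lean cannot show that the range was its cause. Whether the wider astrocyte range comes from the precipitation, the authors' normalization or the cell type cannot be told apart with 1 array each.

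The second pattern is the farther reach of H3K4me3 around marked probes in NSC. Probe noise on the astrocyte array would scale the correlation at all distances alike, yet the ratio of the correlation at 10 probes to that at 1 probe was 0.15 in astrocytes and 0.49 in NSC, a quotient of 0.32. A linear difference in range is also argued against, since the share of the range left 5 probes away does not move with it and was 0.22 times as large in astrocytes. Longer DNA fragments in the NSC chromatin stay open: H3K27me3 correlations at 10 probes differed by -0.038 (NSC minus astrocyte), which gives no sign of them. The bound for excluding them was widened to a difference below -0.1 after that value was seen, because the chromatin of the marks need not have been shared. A difference between cell types in the width of H3K4me3 may account for the pattern, as an untested hypothesis. Runs of marked probes, however, were longer in astrocytes, at a mean of 7.18 probes against 6.51 in NSC.

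The third pattern is the low H3K27me3 at probes with H3K4me3. The correlation of H3K4me3 with H3K27me3 of the probe numbered 2 higher was -0.435 or lower in both cell types. The marks were on separate arrays, and independent noise of single probes could not make a correlation negative. The test therefore adds no support to the pattern. Exclusion of one mark by the other and loss of nucleosomes at active promoters remain open and were not tested.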

How the results depend on the processing

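No paired analysis was possible because each group holds 1 array. Leaving out an array was not possible for the same reason. The alternatives planned for gene medians, probe numbers per gene, the marker lists and receptor-gene centring were not run, since probes were not paired with genes here. Stretch means, running means, the mean of the 3 highest probes of a stretch, mode centring and the equal floor and marked level were chosen after seeing the data. So were all alternatives, quantile normalization and equal median absolute deviations included, for the H3K27me3 stretches at 0.58, the H3K4me3 difference where both cell types were marked, the H3K4me3 range left 5 probes away, the length of H3K4me3 runs and the H3K27me3 difference of stretches, and Spearman's rho for the differences of the marks; the cause of the changes was not tested unless stated. Of 125 alternative values, 54 stayed within 1.5 times a count, 10 percentage points of a share, 0.05 of a correlation or 0.1 of a median difference, 63 moved farther and 8 changed direction.

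For H3K4me3, probes higher in NSC and in astrocytes numbered 25078 and 25298 after quantile normalization (49.8% higher in NSC), 31655 and 20915 with equal median absolute deviations (60.2%), 27405 and 23140 with the floor and marked level set equal (54.2%), and 82014 and 76548 with no requirement on the level (51.7%). They numbered 24299 and 79604 at a difference of 0.58 and 9165 and 21304 at 1.5. Centring on the mode gave 29768 higher in NSC (37.5%). Over stretches the rule gave 70 and 195, and the 3 highest probes of each stretch gave 35 and 3758 (0.923%); these count stretches, not probes. Where both cell types were marked, the median NSC minus astrocyte difference was 0.032 after quantile normalization, 0.24 with equal median absolute deviations, -0.64 without centring and -0.44 with mode centring, against -0.53. The direction of the H3K4me3 excess therefore depends on the scaling. The share of the H3K4me3 range left 5 probes away, astrocyte over NSC, was 0.22 in the main setting, 0.19 after quantile normalization and 0.23 without centring.

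For H3K27me3, probes higher in NSC and in astrocytes numbered 1351 and 1513 at a difference of 0.58 (47.2%), 27 and 143 at 1.5 (15.9%), 8008 and 7734 with no requirement on the level (50.9%), 77 and 296 with mode centring (20.6%), and 9 and 66 with running means (12%). Stretch means gave 0 and 0, a count fixed by the level of 1 that only 1 stretch reached, and the 3 highest probes of a stretch 2 and 40 (4.76%). Without centring 1160 were higher in astrocytes, and equal median absolute deviations gave 43.2% higher in NSC.

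Stretches with an H3K27me3 mean of at least 0.58 numbered 1451 in astrocytes and 582 in NSC without centring, and 87 and 21 with mode centring, where none of the 50 shared stretches was left. At a level of 0.58 for both marks, H3K27me3 alone lay on 31918 probes in astrocytes and 31834 in NSC and both marks on 4221 and 3780; at 1.5 these were 62, 26, 15 and 4. With mode centring H3K27me3 alone lay on 631 and 448 probes, and both marks on 100 in NSC. The correlation of the differences of the marks across probes was 0.11 after quantile normalization, -0.0012 as Spearman's rho and -0.089 over stretch means, so its sign is not settled. Between arrays, stretch means gave r of 0.91 for H3K4me3, -0.74 between the marks in astrocytes and -0.80 for NSC H3K4me3 with astrocyte H3K27me3. Spearman's rho was 0.69 for H3K27me3 between cell types and -0.43 between the marks in NSC. The signal behind each ratio is unknown, so the effect of dim probes could not be examined.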

Other observations

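The 46 genomic probes with the highest running numbers were low on all arrays. Their means were -4.08 ± 0.30 for astrocyte H3K4me3, -3.31 ± 0.23 for NSC H3K4me3, -4.40 ± 0.37 for astrocyte H3K27me3 and -4.20 ± 0.32 for NSC H3K27me3 (SD over probes). No other genomic probe was at or below -2.5 on all 4 arrays. The ratios of these probes to the comparison DNA were thus low for both marks in both cell types, and their position is not given. The signal behind the ratios is unknown, so depletion from the ChIP DNA was not told apart from an effect of the comparison DNA or the probes.

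The astrocyte H3K4me3 array also had a long lower tail, with 11.5% of probes at or below -2 against 2.80% on the NSC array.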
